A study of Mus musculus with 2 samples.

How the data were processed

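ATAC-seq was performed on nuclei of C57BL/6 bone marrow-derived macrophages, 1 library from cells kept in GM-CSF for 7 days and 1 from cells kept in M-CSF for 7 days. Per the labels' protocols, nuclei were treated with Tn5 transposase and libraries were sequenced on an Illumina HiSeq instrument. The libraries were grouped by the treatment in their labels.

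The files used were the authors' lists of annotated peaks, 1 per library, so peaks had been called per sample and nothing had been pooled. Per the submitters' processing notes, Bowtie 0.12.2 was used with the genome build mm9. The peak caller, its control, any shift of reads for the transposase and any filters were not given in the sources used here. The gene positions in the files were those of the later build GRCm38. The start of the gene lay within 100 bp of its GRCm38 position for 70.4% of the 10635 genes compared in the GM-CSF list and 68.1% of the 7704 in the M-CSF list. The summits of 75.2% and 74.5% of promoter peaks lay within 200 bp of the gene start in the file, so peaks and genes were on one coordinate system. Coordinates are therefore given as the files hold them, taken as GRCm38 and counted from 1.

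Per the file headers, the authors' files give each peak a fold enrichment, which is a ratio over the caller's background. They also give the deposited −log10 p and −log10 q of each peak, and a score. In every entry the authors' score equalled 10 times the −log10 q rounded down, and the score was not used further. The smallest −log10 q was 1.30 in the GM-CSF list and 1.31 in the M-CSF list, close to a q of 0.05. Fold enrichment was used only to describe, rank and filter peaks within a list, since ranks from lists of unequal length show no change.

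Each line of a file pairs 1 peak with 1 element of an overlapping gene, which is a promoter of 2 kb upstream, a UTR, an exon or an intron. The GM-CSF file had 130292 such lines and the M-CSF file 81863, for 25542 and 16570 distinct intervals. Several summits in an interval were merged to 1 peak with the largest fold enrichment. Peak numbers ran to 36565 and 23737, and 69.9% and 69.8% of the numbers had a line. Peaks without a line overlapped no gene element or were otherwise left out, and were not analysed here. Enhancers between genes are therefore not covered.

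Peaks were compared by overlap of at least 1 bp. Because read numbers are unknown, comparisons were repeated with the strongest 16570 peaks of each library, the length of the shorter list. This cut removed GM-CSF peaks alone, down to a fold enrichment of 3.95, and kept every M-CSF peak. Genes and lists with weak GM-CSF peaks therefore move toward M-CSF by the cut itself. Each peak was placed in 1 class in the order promoter, 5′ UTR, exon, 3′ UTR, intron. A gene's peaks were those the files assign to it by any element, and 1 peak can belong to several genes. Exact Clopper-Pearson 95% intervals were computed for shares. Per gene, log2 of GM-CSF peaks plus 1 over M-CSF peaks plus 1 was centred on the median of genes with a like total. A list's median was set against 10000 random lists of the same size matched on total peaks. Expected overlap was computed from peaks of the same element class in groups of like fold enrichment, like −log10 q, or both, and intervals for the difference came from resampling genes.

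Before the data were examined, the groups, the comparisons, the main alternatives, 23 gene lists and the rule for named genes were fixed. The lists covered M-CSF macrophage and GM-CSF or dendritic programmes, MHC class II, cytokines, chemokines, H3K27 methylation, myeloid transcription factors, pattern recognition, interferon response, lipid handling, osteoclasts, matrix proteases, cell cycle, housekeeping and developmental regulators. They also covered markers of neutrophils, T cells, B cells, natural killer cells, erythroid cells, mast cells with basophils and eosinophils, plasmacytoid dendritic cells and stromal cells. Of the 439 list genes, 293 had at least 1 peak and 438 were found in a table of gene names of GRCm38, which was used only to check names and the build.

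The rule named 11 genes in any case. It added up to 4 genes per list with the largest absolute centred ratio among those with 5 or more peaks, and 10 genes in each direction over all genes. It also added 10 genes in each direction with the strongest promoter peak in one list alone. For the ranking over all genes the minimum was 10 peaks, because only 47 genes reached 20. Not every gene that the rule named is reported here. The gene lists' random comparison was tested on simulated data over 18417 genes. It called 3% of 100 unchanged lists and 93% of 100 lists with a shifted share by the median, and 5% and 100% by the GM-CSF share of peaks. The simulated GM-CSF share of the shifted lists was above that of any list here, so these rates do not show how often a smaller shift would be found. The overlap code gave the same result as a pairwise search in every simulated case. The comparison of the 4 highest lists with the 4 highest of 22 random lists was added after the data were seen. In simulated lists with the same shift and, unlike the real ones, of equal size, it called 3% of 100 unchanged and 100% of 100 changed sets. An earlier form, which drew random lists for these 4 without repeating the choice, put their share at equal length at percentile 100 and was replaced. The reading that the new form leaves the question open when the share is ordinary with all peaks too was settled after its values were seen. By its resampled interval, the matched overlap comparison called 0% of 50 unchanged and 100% of 50 lowered sets, where the simulated lowering was larger than the differences of the 4 highest lists. These rates do not cover the percentiles of overlap among random draws. Those draws treat peaks of the same gene as independent.

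The alternatives tried were other overlap rules, the stronger part of each list, autosomes with X, every line in place of distinct intervals, removal of the widest peaks, other pseudocounts, unmatched random lists and genes with more peaks. Distances of 1 kb, 5 kb or 50 kb were not run, since the files hold no distance column. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.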

Results

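Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase cuts and tags accessible DNA, in bone marrow-derived macrophages of C57BL/6 mice. Macrophages grown from bone marrow for 7 days in granulocyte-macrophage colony-stimulating factor (GM-CSF) were set against macrophages grown for 7 days in macrophage colony-stimulating factor (M-CSF). GM-CSF yields cells with inflammatory and dendritic traits, and M-CSF is the growth factor that maintains most tissue macrophages. The study concerns histone H3 lysine 27 methylation and the transcription of macrophage cytokine genes, and the comparison asks where accessible chromatin differs between the cultures. Each condition was represented by 1 library, so no difference has a replicate check and no test between the conditions was made. The values describe these 2 libraries. The exact (Clopper-Pearson) 95% intervals cover counting error only. They treat peaks as independent, although a gene can hold several peaks and a shared site counts in both lists. For gene lists they can therefore be too narrow.

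The GM-CSF list held 25542 distinct peaks, assigned to 16487 genes, and the M-CSF list held 16570 peaks, assigned to 12934 genes. Peaks had a median width of 211 bp in the GM-CSF list and 191 bp in the M-CSF list, and covered 6290 kb and 3738 kb. The median fold enrichment, which is the authors' own value for each peak and was used only within a list, was 4.44 in the GM-CSF list and 3.44 in the M-CSF list. Read numbers were not given in the sources used here, so the depth of each library is unknown. A gene without a peak in a list can still have had accessible chromatin below that list's threshold.

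The cytokine genes at the centre of the study had peaks mostly in the GM-CSF list. For Tnf the centred log2 ratio was 0, so its excess was that of the median gene with a like total. The ratio was also 0 for Il6, Il12b, Il23a and Il10, but each had 1 peak in all. A gene with 1 peak can only take 0 or, with an M-CSF peak, −2, so its ratio could not show an excess of GM-CSF peaks. Il6, which encodes an inflammatory cytokine, had a peak over its promoter and first transcribed bases in the GM-CSF list (chromosome 5, 30013194 to 30013345, fold enrichment 4.80) and no peak in the M-CSF list. Il12b, which encodes the subunit shared by interleukin-12 and interleukin-23, had a promoter peak in the GM-CSF list alone (chromosome 11, 44398819 to 44398998, 4.04). Il23a, which encodes the other interleukin-23 subunit, likewise had a peak over its promoter and an exon in the GM-CSF list alone (chromosome 10, 128298378 to 128298617, 3.95), which was not among the strongest 16570 GM-CSF peaks. Il10, which encodes an anti-inflammatory cytokine, had an intronic peak in the GM-CSF list alone (chromosome 1, 131021031 to 131021218, 4.13). GM-CSF peaks were also split into 10 groups of equal size by fold enrichment. In the groups that held these Il6, Il12b, Il23a and Il10 peaks, 13.5% to 23.8% of peaks were overlapped by an M-CSF peak. Absence from the M-CSF list was thus usual for GM-CSF peaks of this strength when element classes were pooled. Over all strengths, 6638 of 12267 GM-CSF promoter peaks were overlapped by an M-CSF peak, against 2097 of 11040 intronic ones. The share for promoter peaks of this strength was not computed. Whether absence was usual for peaks like those of Il6, Il12b and Il23a, which overlapped promoters, is therefore not shown.

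Tnf, which encodes tumour necrosis factor, had a peak inside the gene in both lists, at chromosome 17, 35200462 to 35200804 in GM-CSF macrophages and 35200575 to 35200780 in M-CSF macrophages. A second Tnf peak, over the promoter (35202170 to 35202321, fold enrichment 2.97), was in the GM-CSF list alone and was not among its strongest 16570 peaks. Il1b, another inflammatory cytokine gene, had no assigned peak in either list. Il16, which encodes a T cell chemoattractant, had 9 peaks in the GM-CSF list (4 of the strongest 16570) and 0 in the M-CSF list, of which none was over a promoter. Il15, which encodes a cytokine that sustains lymphocytes, had 4 peaks in the GM-CSF list and 2 in the M-CSF list, and its promoter peak was in the GM-CSF list alone. Of the 24 cytokine genes examined, 3 had a promoter peak in both lists, 8 in the GM-CSF list alone and 0 in the M-CSF list alone. The 3 with both were Il18, Ebi3 and Tnfsf13b. Over the whole list, 33 GM-CSF and 11 M-CSF peaks were assigned, a GM-CSF share of 75% (95% interval 59.7 to 86.8). At equal length the promoter peak was in both lists for 3 genes and in the GM-CSF list alone for 4, with 20 and 11 peaks (64.5%). Lif and Il1rn each had 1 peak, in the M-CSF list alone. The 5 genes Il18, Ebi3, Tnfsf13b, Lif and Il1rn lay outside the rule for named genes and were chosen after their values were seen.

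The genes of the receptors for the growth factors had as many peaks or more in the GM-CSF list, with a centred log2 ratio of 0 for Csf2ra and Csf2rb. Csf1r, which encodes the M-CSF receptor, had 4 peaks in the GM-CSF list and 1 in the M-CSF list, and 2 and 1 with the strongest 16570 peaks of each library, where its centred log2 ratio fell from 0.907 to 0. The shared peak was intronic, at chromosome 18, 61108372 to 61108872 in GM-CSF macrophages, and the Csf1r promoter peak (61105677 to 61105940, fold enrichment 3.18) was in the GM-CSF list alone and below its strongest 16570. Csf2ra, which encodes the alpha chain of the GM-CSF receptor, had 2 GM-CSF peaks and 1 M-CSF peak, and the peak at its 5′ exon was shared. Csf2rb, which encodes the common beta chain, had 1 promoter peak in each list, at chromosome 15, 78325701 to 78326029 in GM-CSF macrophages. Reads from Csf2rb and its close paralog Csf2rb2 can be confused.

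The genes of the H3K27 methylation machinery had promoter peaks in both libraries nearly throughout. Of 13 genes, 11 had a promoter peak in both lists, and Ezh1, which encodes a methyltransferase of Polycomb complex 2, had one in the GM-CSF list alone. Ezh2, the other methyltransferase, had a promoter peak at chromosome 6, 47594938 to 47595288 in the GM-CSF list and at 47594937 to 47595288 in the M-CSF list, with 3 and 1 assigned peaks in all. Kdm6b, which encodes a demethylase of the mark, had 3 GM-CSF peaks and 1 M-CSF peak, none assigned to its promoter, and the peak at its 5′ exon was shared. With lists of equal length Ezh2 and Kdm6b had 2 and 1 each, and their centred ratios fell from 1 to 0. Eed had 3 peaks in each list, Jarid2 had 6 and 5, and Aebp2 had 2 and 3. The list as a whole had 26 GM-CSF and 23 M-CSF peaks (53.1%, interval 38.3 to 67.5), and 20 and 23 at equal length (46.5%).

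Genes of both macrophage programmes had more peaks in the GM-CSF list. Of 30 genes known from M-CSF and resident macrophages, 8 had a promoter peak in both lists, 10 in the GM-CSF list alone and 0 in the M-CSF list alone, with 55 and 21 peaks (72.4%, interval 60.9 to 82.0). At equal length the genes numbered 7, 6 and 1 and the peaks 38 and 21 (64.4%). Mertk, which encodes a receptor for apoptotic cells, had 8 GM-CSF and 2 M-CSF peaks, or 4 and 2 at equal length. Cx3cr1, which encodes the fractalkine receptor, had 10 and 4, and the membrane protein gene Ms4a7 had 4 and 1, or 2 and 1 at equal length. Mertk had a promoter peak in both lists, and those of Cx3cr1 and Ms4a7 were in the GM-CSF list alone, the Ms4a7 one (fold enrichment 3.38) below its strongest 16570. Of 30 genes known from GM-CSF macrophages and dendritic cells, 3 had a promoter peak in both lists, 9 in the GM-CSF list alone and 0 in the M-CSF list alone, with 34 and 10 peaks (77.3%, interval 62.2 to 88.5), and 3, 7 and 0 genes with 24 and 10 peaks (70.6%) at equal length. Pparg, which encodes a lipid-sensing nuclear receptor, had 7 and 2 peaks (4 and 2 at equal length), and Cd83, a marker of mature dendritic cells, had 4 and 1. Cd86, which encodes a costimulatory ligand, had 3 and 2.

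Of 32 myeloid transcription factor genes, 17 had a promoter peak in both lists, 11 in the GM-CSF list alone and 0 in the M-CSF list alone, with 82 and 38 assigned peaks (68.3%, interval 59.2 to 76.5). With lists of equal length the genes numbered 16, 6 and 1 and the peaks 51 and 38 (57.3%). Spi1, which encodes the macrophage master regulator PU.1, had 5 GM-CSF peaks and 1 M-CSF peak, and 1 in each list at equal length. The shared Spi1 peak was intronic (chromosome 2, 91082970 to 91083239 in GM-CSF macrophages), and the promoter peak at 91096594 to 91096802 (fold enrichment 3.45) was in the GM-CSF list alone and below its strongest 16570. Runx1, a regulator of blood cell development, had 10 and 2 peaks (5 and 2 at equal length), and Irf2, an interferon regulatory factor, had 7 and 3. Nfkb1, which encodes an NF-kB subunit, had 2 GM-CSF and 3 M-CSF peaks.

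**Figure D1:**
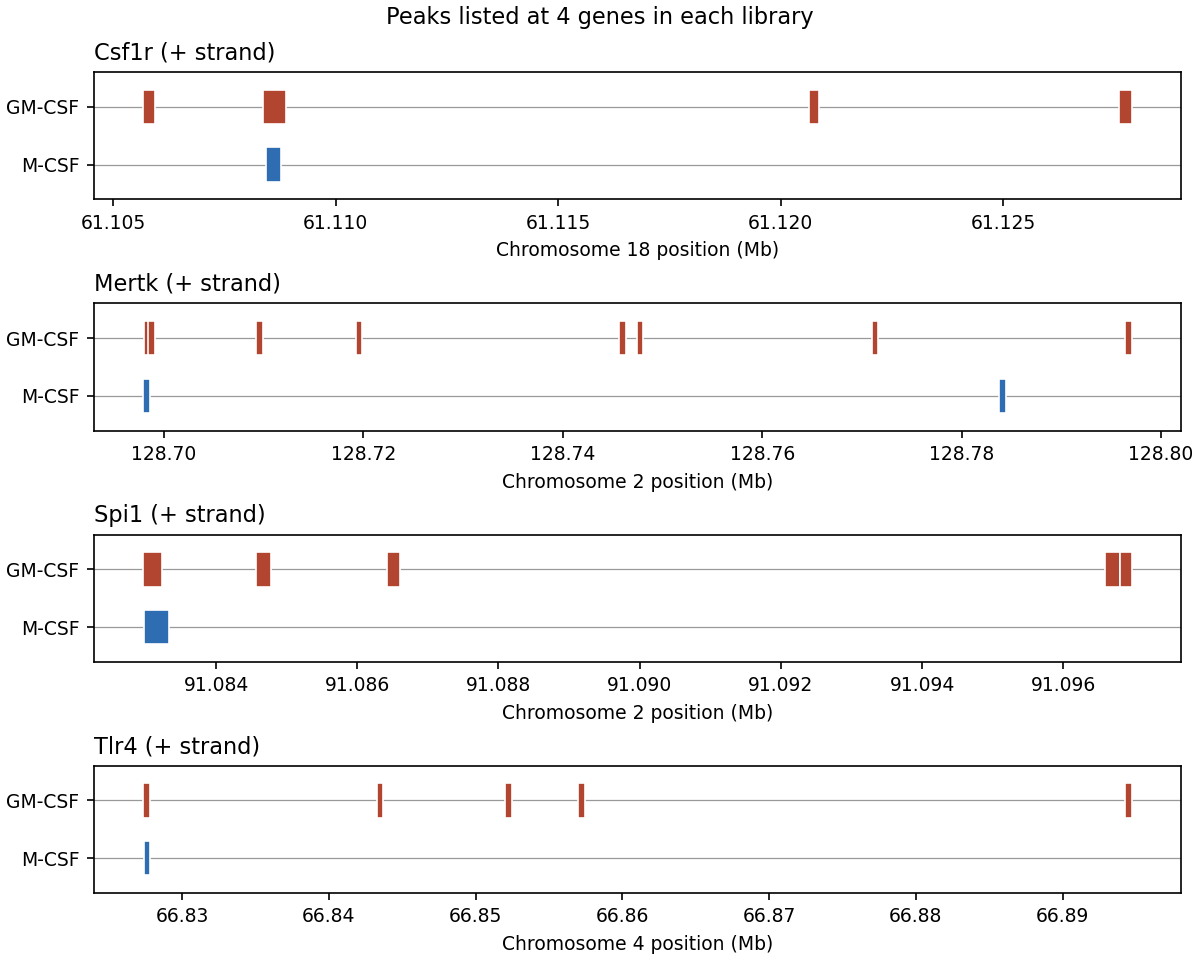
Positions in Mb of the peaks listed at Csf1r, Mertk, Spi1 and Tlr4, with GM-CSF peaks in the upper lane and M-CSF peaks in the lower lane of each panel. Each block is 1 peak, the narrow ones drawn wider than their length so that they can be seen, and each gene has 1 peak in the M-CSF lane except Mertk, which has 2. All listed peaks are drawn, and of the GM-CSF peaks 2 at Csf1r, 4 at Mertk, 1 at Spi1 and 4 at Tlr4 are among the strongest 16570.

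Innate sensing and lipid genes included further loci with most of their peaks in the GM-CSF list, but the GM-CSF share over all genes was already 60.3%. By this share the pattern recognition list lay at percentile 88.12 of random lists and the lipid list at 92.35. At equal length the percentiles were 74.17 and 92.745. Tlr4, which encodes the lipopolysaccharide receptor, had 5 GM-CSF peaks and 1 M-CSF peak, and shared the promoter peak at chromosome 4 (66827378 to 66827800 in GM-CSF macrophages). Nod2, which encodes a cytosolic sensor of bacterial wall fragments, had 6 and 1, with the promoter peak in the GM-CSF list alone. Irak2, a kinase gene of Toll-like receptor signalling, had 5 and 4, and the inflammasome gene Nlrp3 had 3 and 2, but at equal length they had 3 and 4, and 1 and 2. The pattern recognition list had 11 genes with a promoter peak in both lists, 4 in the GM-CSF list alone and 0 in the M-CSF list alone, with 42 and 22 peaks (65.6%, interval 52.7 to 77.1), but 10, 1 and 1 genes and 25 and 22 peaks (53.2%) at equal length. Among lipid-handling genes, the scavenger receptor gene Msr1 had 6 and 1 peaks and the cholesterol transporter gene Npc1 had 5 and 2, while Soat1 had 5 and 4 and Abca1 had 7 and 5. That list had 9 genes with both promoter peaks and 5 with the GM-CSF one alone, and 57 and 29 peaks (66.3%, interval 55.3 to 76.1), or 37 and 29 (56.1%) at equal length. Of the 42 GM-CSF pattern recognition peaks, 18 were overlapped by an M-CSF peak, against 12.8 at like fold enrichment and class (percentile 97.995). The interval of that difference was wide (12.4 points, −1.86 to 29.5). Of the 22 M-CSF peaks of that list, 19 were overlapped, against 12.9 (percentile 99.94). These overlap values were picked out after they were seen.

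The antigen presentation, chemokine and interferon lists each included 1 gene with a promoter peak in the M-CSF list alone. Of 13 genes of MHC class II presentation, 3 had a promoter peak in both lists, 5 in the GM-CSF list alone and 1 in the M-CSF list alone, with 15 and 7 peaks (68.2%, interval 45.1 to 86.1), or 11 and 7 at equal length. Of 24 chemokine genes, 6 had a promoter peak in both lists, 5 in the GM-CSF list alone and 1 in the M-CSF list alone, with 16 and 9 peaks (64.0%, interval 42.5 to 82.0). The chemokine genes numbered 6, 3 and 1 at equal length, and their peaks 11 and 9. Of 22 interferon response genes, 7 had both, 3 the GM-CSF one alone and 1 the M-CSF one alone, with 16 and 14 peaks (53.3%, interval 34.3 to 71.7). With all peaks the interferon list was already below the GM-CSF share over all genes, 60.3% (percentile 12.4 of random lists). At equal length it had 8 GM-CSF and 14 M-CSF peaks (36.4%, percentile 3.05). A promoter peak was then in the GM-CSF list alone for 1 gene and in the M-CSF list alone for 2.

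Osteoclast genes had 19 GM-CSF and 10 M-CSF peaks (65.5%, interval 45.7 to 82.1) and 10 in each list at equal length. With all peaks Itgb3, an integrin gene, had 3 in each list and the proton pump gene Atp6v0d2 had 3 and 2. Genes of matrix proteases and their inhibitors had 19 and 11 (63.3%, interval 43.9 to 80.1), where Adam17, which encodes the enzyme that releases tumour necrosis factor, had 3 and 2. Cell cycle genes had 32 and 26 (55.2%, interval 41.5 to 68.3), with 11 promoters in both lists and 8 in the GM-CSF list alone, and 25 and 26 peaks, 11 and 6 promoters at equal length. Cdk6, which encodes a kinase of the G1 phase, had 7 GM-CSF and 9 M-CSF peaks. Housekeeping genes had 18 promoters in both lists and 4 in the GM-CSF list alone, with 34 and 26 peaks (56.7%, interval 43.2 to 69.4), or 26 in each list at equal length. Polr2a had 5 and 2 peaks and Tbp had 3 and 2.

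With all peaks, the homeobox and developmental regulator list was the one with more M-CSF than GM-CSF peaks among the lists with at least 20 peaks. At equal length, where GM-CSF peaks alone are removed, the interferon, H3K27 machinery and cell cycle lists had more M-CSF peaks too, as given above. The homeobox list then had 3 and 16 (15.8%). With all peaks the homeobox list had 10 GM-CSF and 16 M-CSF peaks (38.5%, interval 20.2 to 59.4), spread over 17 of its 36 genes. A promoter peak was in both lists for 3 genes, in the GM-CSF list alone for 3 and in the M-CSF list alone for 2, and at equal length for 1, 1 and 4. No member reached the 5 peaks required for naming by the rule.

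Among markers of other blood and stromal cells, those of plasmacytoid dendritic cells had the most peaks. Neutrophil markers had 4 GM-CSF and 6 M-CSF peaks, with Cebpd at 2 and 3. T cell markers had 4 and 5, natural killer cell markers 2 and 3, and markers of mast cells, basophils and eosinophils 2 and 3. B cell markers had 9 and 5, of which the transcription factor gene Ebf1 held 4 and 3. Erythroid and megakaryocyte markers had 8 and 3, of which Ank1 held 4 and 1. Plasmacytoid dendritic cell markers had 21 and 13, with Runx2 at 9 and 6, Tcf4 at 7 and 5 and Ccr9 at 3 and 2. Stromal and endothelial markers had 12 and 5, with Pecam1, which monocytes also express, at 4 and 2. The equal-length cut removes weak GM-CSF peaks and no M-CSF peaks, so shifts toward M-CSF can come from the cut itself. At equal length the erythroid list turned to 1 and 3, with Ank1 at 0 and 1 and promoter peaks in the M-CSF list alone at 2 genes and in the GM-CSF list alone at 0. B cell markers then had 5 and 5, with Ebf1 at 2 and 3, plasmacytoid markers 15 and 13, with Tcf4 at 4 and 5, stromal markers 9 and 5, with Pecam1 at 2 and 2, neutrophil markers 2 and 6, T cell markers 1 and 5, and mast cell, basophil and eosinophil markers 0 and 3.

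Over all genes, 31598 GM-CSF and 20813 M-CSF peak assignments were made, a GM-CSF share of 60.3%, against which each list was set. The planned measure was the list's median log2 ratio of GM-CSF to M-CSF peaks, centred on genes with a like total. Compared with 10000 random lists matched on total peaks, this median was in the upper 2.5% for 0 of 22 lists and in the lower 2.5% for 1, the homeobox list (−1, percentile 0.365). The median was 0 in 18 lists, so it separated few of them. The list of mast cell, basophil and eosinophil markers, of which 2 genes had a peak, was not ranked. The GM-CSF share of a list's peaks, a measure added after the data were seen, lay in the upper 2.5% of random lists for 4 lists, at the percentiles given here. These were the M-CSF macrophage (99.84), GM-CSF and dendritic (99.845), cytokine (99.05) and myeloid transcription factor (99.255) lists. Their pooled share (71.8%) lay at percentile 88.6 when the 4 highest of 22 random lists were picked in the same way. The share lay in the lower 2.5% for the homeobox list (0.055). With the strongest 16570 peaks of each library, the transcription factor list was at 96.375 and the other 3 stayed in the upper 2.5%, and the share over all genes was 50.3%.

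**Figure D2:**
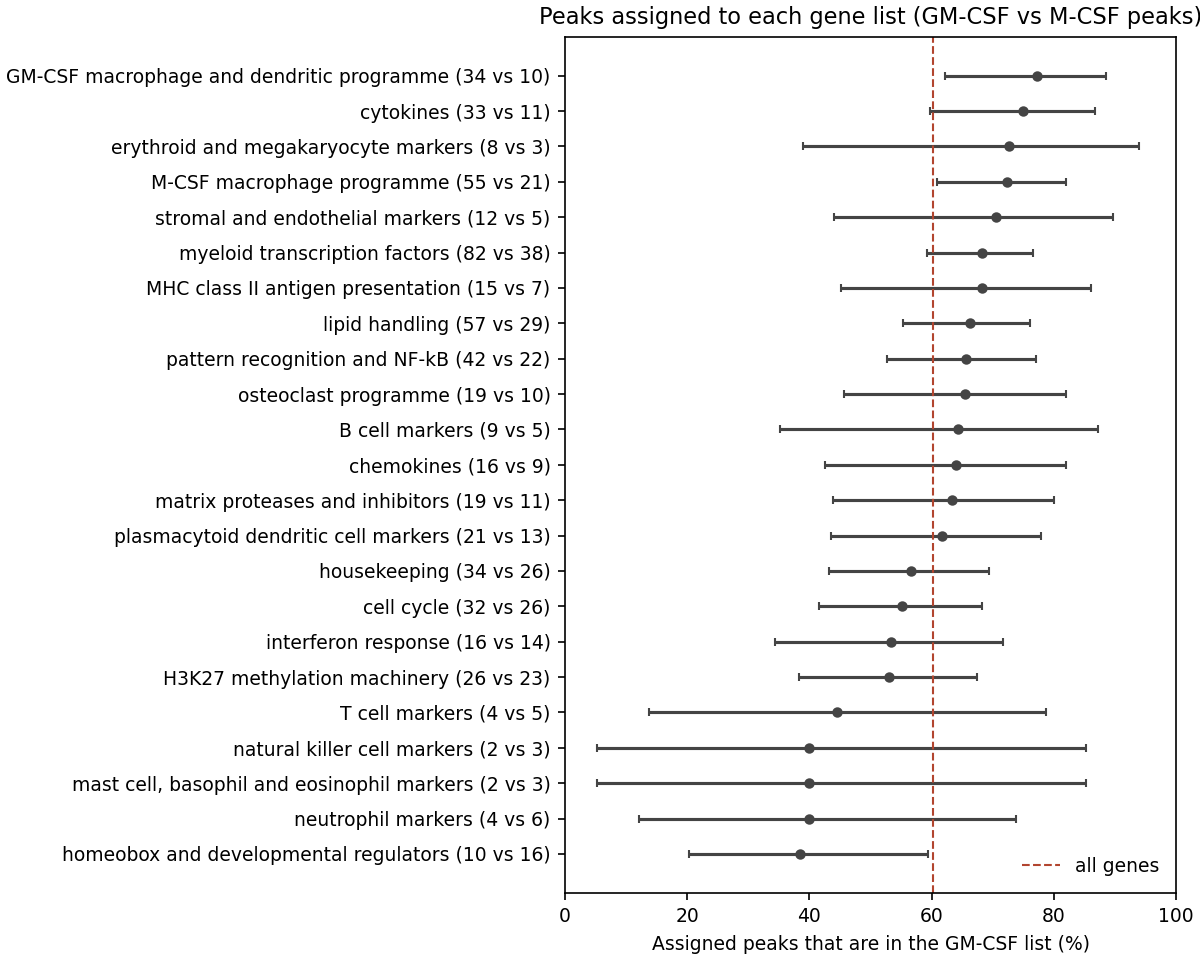
Share, in percent, of the peaks assigned to each gene list that are in the GM-CSF list, with exact 95% intervals over peaks as bars, and the numbers of GM-CSF and M-CSF peaks beside each name. The dashed line is the share over all genes, 60.3%, and the homeobox list is the lowest at 38.5%.

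Among single genes with at least 10 assigned peaks, those with the largest centred excess of GM-CSF peaks were long genes with mostly intronic peaks. Fmnl2, which encodes an actin-nucleating formin, and Gpc5, a glypican gene, each had 11 GM-CSF peaks and 1 M-CSF peak (centred log2 ratio 1.91). Pde4d, which encodes a cyclic AMP phosphodiesterase, had 29 and 6 (1.42). Others were 1110051M20Rik, Cog5, Gm30382 and Gtdc1 (9 and 1 each, 1.74), Rabgap1l (13 and 2, 1.54) and the transcription factor gene Rreb1 (12 and 2, 1.44). The counts and the GM-CSF promoter fold enrichment (4.46) of 1110051M20Rik and Gm30382 were the same, so these may be the same peaks assigned to both. At equal length Fmnl2 had 4 and 1, Gpc5 10 and 1 and Pde4d 19 and 6.

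The largest M-CSF excess was at a cluster of related genes near 85 Mb of chromosome 1. A530032D15Rik had 3 GM-CSF and 11 M-CSF peaks (−2.26), and C130026I21Rik, whose annotated span contains those peaks, had 12 and 30 (−1.93). The copies in this cluster are similar, so reads can be shared among them. Copg2, which encodes a coat protein of transport vesicles, had 3 and 8 (−1.85), of which 6 M-CSF peaks lay close together in introns between 30803667 and 30805753 on chromosome 6. Mroh2a also had 3 and 8 (−1.85). Fto, an RNA demethylase gene, Igsf5, Ltbp1, the mineralocorticoid receptor gene Nr3c2 and Tenm3 each had 3 and 7 (−1.58), and Cfap54 had 4 and 8 (−1.53). At equal length, where GM-CSF peaks alone are removed, Mroh2a had 0 and 8 (−3.17), Cfap54 1 and 8 and Igsf5 1 and 7.

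Promoter peaks were found at 13007 genes, of which 7805 had one in both lists, 4281 in the GM-CSF list alone and 921 in the M-CSF list alone. Thus 35.4% (34.6 to 36.3) of the 12086 genes with a GM-CSF promoter peak lacked one in the M-CSF list, and 10.6% (9.92 to 11.2) of the 8726 genes with an M-CSF promoter peak lacked one in the GM-CSF list. With the strongest 16570 peaks of each library, 7474 genes had both, 2998 the GM-CSF one alone and 1252 the M-CSF one alone. Genes with predicted or RIKEN clone names made up 13.4% of the genes with both, 22.1% of those in the GM-CSF list alone and 37.9% of those in the M-CSF list alone.

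The promoter peaks of Gm43416, Gm26808, Mocs1 and Shcbp1 were the strongest of the GM-CSF list alone. Mki67, which encodes the proliferation antigen Ki-67, had its promoter peak at chromosome 7, 135716395 to 135716739 (fold enrichment 11.03). Shcbp1, a gene of dividing cells, had one at chromosome 8, 4779422 to 4779757 (12.0), and Mocs1, an enzyme gene of molybdenum cofactor synthesis, at chromosome 17, 49428190 to 49428466 (12.3). Cyb5rl and Mrpl37 shared 1 peak at chromosome 4, 107066781 to 107067041 (11.03). The others were Gm43416 (16.1), Gm26808 (13.3), 6820431F20Rik (11.9), AC120002.2 (11.5) and Zfp994 (10.98). The promoter peaks of Gm43416 and AC120002.2 overlapped M-CSF peaks that were assigned to exons, so these sites were open in both lists.

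The strongest promoter peaks of the M-CSF list alone were mostly at predicted genes and pseudogenes. Runx1t1, which encodes a transcriptional corepressor, had 2 such peaks at chromosome 4, 13750551 to 13750708 (fold enrichment 5.21) and 13751029 to 13751209 (4.44). Dnah7b, an axonemal dynein gene, had one at chromosome 1, 46066669 to 46066836 (4.83). The others were Gm8126 and Gm8127 (5.41 each), Gm6264 (5.21), Gm27552 (5.21), Gm26778 (5.08), Hmgb1-ps5 and n-TSaga9 (4.996 each) and Gm10553 (4.91). Gm6264 and Gm10553 lay in the same chromosome 1 cluster as A530032D15Rik.

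Over the whole lists, 9182 of the 25542 GM-CSF peaks (35.9%, interval 35.4 to 36.5) overlapped an M-CSF peak by at least 1 bp, and 9282 of the 16570 M-CSF peaks (56.0%, 55.3 to 56.8) overlapped a GM-CSF peak. The other 16360 and 7288 peaks were in one list alone. With lists of equal length, 16570 peaks each, the shares were 49.7% (49.0 to 50.5) of the GM-CSF peaks and 50.6% (49.8 to 51.3) of the M-CSF peaks. Shared peaks were the stronger ones within each list. The median fold enrichment of GM-CSF peaks was 6.72 for shared peaks and 3.97 for the rest, and that of M-CSF peaks was 3.87 and 3.14.

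**Figure D3:**
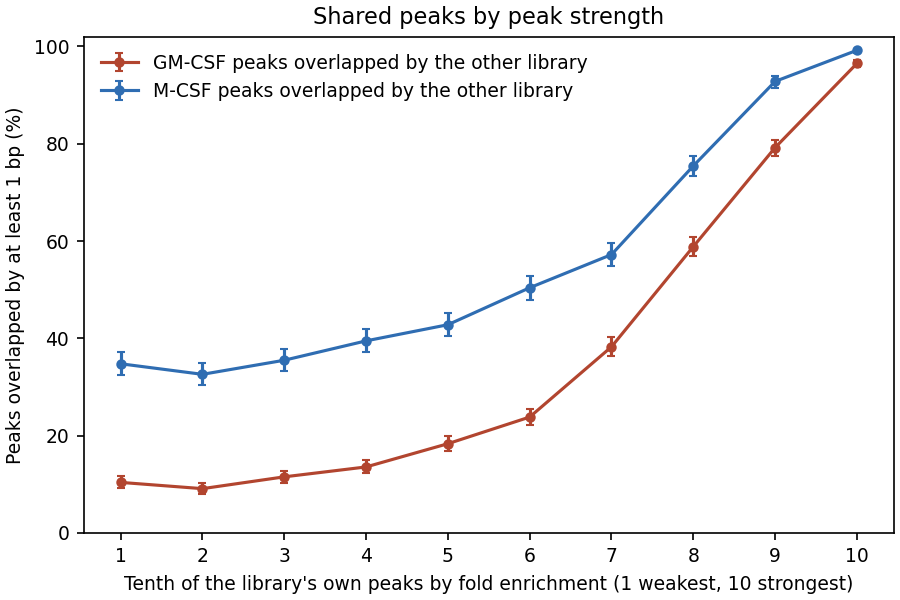
Share, in percent, of each library's peaks that overlap a peak of the other library by at least 1 bp, with the library's own peaks split into 10 groups of equal size by fold enrichment and exact 95% intervals as bars. Among GM-CSF peaks the share is 10.4% in the weakest group and 96.5% in the strongest, and among M-CSF peaks it is 34.8% and 99.2%.

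Promoters made up most shared peaks and introns most peaks of one list alone. A promoter was overlapped by 48.0% (47.4 to 48.6) of all GM-CSF peaks and 49.6% (48.8 to 50.3) of all M-CSF peaks. Of shared peaks, 72.3% of those in the GM-CSF list and 72.2% of those in the M-CSF list overlapped a promoter. Of peaks in one list alone, the share was 34.4% (33.7 to 35.1) for GM-CSF and 20.7% (19.7 to 21.6) for M-CSF. Introns held 54.7% of the peaks of the GM-CSF list alone and 61.5% of those of the M-CSF list alone, and exons held 9.44% and 16.0%. Peaks over no gene element were not analysed here. With the strongest 16570 peaks of each library, 58.3% of GM-CSF peaks and 49.6% of M-CSF peaks overlapped a promoter.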

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

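The tests chosen only after the data were seen were those with peaks within 500 bp, ranking by −log10 q, the promoter share of the stronger part of each list, promoter summits near the gene start, named genes alone, promoter peaks overlapped by any peak, and the GM-CSF share of peaks. No paired analysis was possible because each condition had 1 library. Counting intervals are narrow, so most shares left them under other settings, and the cause was not tested except where the setting itself removes peaks. The overlapped share of GM-CSF peaks was 32.0% and that of M-CSF peaks 54.0% with an overlap of at least 50% of the peak, 31.3% and 48.3% with a reciprocal overlap of that size, 44.2% and 68.5% in the stronger 50% of each list, 43.2% and 53.0% with the strongest 20000 peaks (all M-CSF peaks), 55.6% and 78.7% over all lines, 34.9% and 54.2% without the widest 1%, and 41.1% and 60.2% within 500 bp. At equal length they were 57.9% and 58.4% with 10000 peaks and 51.4% and 52.2% by −log10 q. The promoter share was 58.3% of GM-CSF peaks at equal length, and 65.4% and 63.2% in the stronger 50% of each list. With the 50% overlap, the median fold enrichment was 6.83 for shared and 4.03 for other GM-CSF peaks and 3.90 for shared M-CSF peaks.

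Genes with a promoter peak in M-CSF alone numbered 544 with the summit within 500 bp of the gene start and 572 without predicted and RIKEN genes, against 921. Lists in the upper 2.5% of random lists numbered 1 with unmatched random lists, 1 with members of 5 or more peaks and 4 by the GM-CSF share of peaks, against 0. Lists in the lower 2.5% numbered 2 with unmatched random lists and 0 with members of 5 or more peaks, against 1. The list medians under other settings show little, since the median was 0 in 18 of 22 lists. Intervals of single genes are too wide to show stability, and of 34 named genes with a centred ratio above 0, 24 kept one at equal length, 9 fell to 0 and 1 turned. Of 29 below 0, 23 stayed below, 5 rose to 0 and 1 turned, and of 23 at 0, 19 stayed, 2 rose, 1 fell and 1 lost its peaks. Distances of 1 kb, 5 kb and 50 kb, and equal lists longer than the 16570 M-CSF peaks, could not be run. Unknown depth limits every statement that a peak was in one list alone.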

Other observations

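Several of the tests given here were chosen only after the result was seen. They were those of biological process terms, of promoter genes by strength and of the ratio of promoter genes at equal length (the counts themselves were planned). For the myeloid lists they were those at equal length, against the same choice of random lists, with matching on −log10 q and of M-CSF peaks. For chromosome X they were those at equal length, in the stronger 50% of the list and of M-CSF peaks. Biological process terms in the authors' files were counted among 9385 genes that had a promoter peak in at least 1 list and a term, for 391 terms of 30 or more genes. Immune response genes more often had their promoter peak in the GM-CSF list alone. They numbered 44 of 76 (57.9%, against 31.2% of all genes), and 0 of 1000 shuffles of the genes gave any term as large a deviation. They included Irf8, a regulator of monocyte fate, the antigen presentation genes H2-Ab1, H2-DMb1 and H2-DMb2, the chemokine gene Cxcl10, the cytokine genes Il15, Osm and Csf3, and Tlr9, a receptor for microbial DNA. Inflammatory response genes numbered 65 of 145 (44.8%), a deviation that 112 of 1000 shuffles reached for some term. They included Il6, Il23a, Tnf, Csf1r, Cd14, Cd40, Nod2 and the prostaglandin synthase gene Ptgs2.

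Of promoters open in both lists, terms were ranked in the same way. Genes with the cell cycle term numbered 197 of 262 (75.2%, against 62.8% of all genes), and DNA repair genes 153 of 199 (76.9%), each reached by 3 of 1000 shuffles, while cell division genes numbered 222 of 309 (71.8%, 80 of 1000). In the shorter cell cycle list counted above, 11 of 19 genes with a promoter peak had one in both lists. Genes of the response to endoplasmic reticulum stress numbered 55 of 64 (85.9%, 11 of 1000 shuffles), among them Atf4, Xbp1, Hspa5 and Ern1. Promoter peaks of the M-CSF list alone, which 6.00% of all these genes had, included 11 of 34 homophilic cell adhesion genes (32.4%, 1 of 1000 shuffles) and 21 of 112 G-protein coupled receptor signalling genes (18.8%, 2 of 1000). The former were mostly predicted genes and the latter included several olfactory receptor genes. Of the same 112 genes, 48 had their promoter peak in the GM-CSF list alone (42.9%, against 31.2% of all genes), a deviation that 805 of 1000 shuffles reached for some term. Neighbouring genes that share a promoter peak are counted separately in these numbers, and genes were not matched on peak strength.

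Many more genes had a promoter peak in the GM-CSF list alone (4281) than in the M-CSF list alone (921). With lists of equal length the ratio was still 2.39, but this cannot decide whether the length of the GM-CSF list is the whole cause. The cut shortened the GM-CSF list alone and kept its strongest peaks, which raised its promoter share, as given above. That raises the ratio by itself. A lower sensitivity of the M-CSF library may account for part of the excess. Of the strongest GM-CSF peaks by fold enrichment, the upper 10%, 96.5% were overlapped by an M-CSF peak. Of the strongest 10% of M-CSF peaks 99.2% were overlapped too, so these shares do not single out the M-CSF library. A wider difference in promoter accessibility between the cultures remains open and was not tested, as each condition had 1 library.

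Peaks of the 4 lists that stood above random lists by GM-CSF share, with 116 genes, numbered 204 in the GM-CSF list and 80 in the M-CSF list (71.8%, interval 66.2 to 77.0), and 133 and 80 at equal length (62.4%, 55.6 to 69.0). The 4 were picked from 22 for that share, and when the 4 highest of 22 random lists were picked in the same way, the pooled share lay at percentile 88.6 with all peaks and 89.82 at equal length. The pooled share thus did not stand apart from such a choice, but the comparison cannot decide the question. Its random lists were picked by percentile and could be smaller than these 4, and the shares of smaller lists vary more. Taken singly with all peaks, the 4 lists lay at percentiles 99.05 to 99.845. Neither the length of the GM-CSF list nor chance in the choice of lists is excluded. Loss of weak or intronic peaks below the M-CSF threshold cannot be told apart from a difference between the cultures either, since the choice of lists lowers the overlap by itself and the answer depends on the measure of strength. Of the 204 GM-CSF peaks, 55 were overlapped, against 61.6 for peaks of like fold enrichment and class (percentile 12.06, the comparison set beforehand), 70.6 for like −log10 q (percentile 0.17) and 70.5 for both (percentile 0.315), and of the 80 M-CSF peaks 58 were overlapped, against 43.7 for like fold enrichment and class (percentile 100), which the choice of lists can raise by itself.

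Chromosome X held 391 GM-CSF peaks (1.53%, interval 1.38 to 1.69) and 161 M-CSF peaks (0.972%, 0.828 to 1.13). With equal lists of 16570, 10000 and 5000 peaks the shares were 2.08% and 0.972%, 2.58% and 1.42%, and 2.64% (2.21 to 3.12) and 1.92% (1.56 to 2.34), so the gap was narrower among the strongest 5000, while the overlap deficit at like fold enrichment was no smaller in the stronger 50% of the list (−22.2 points, −26.9 to −17.5). Loss of weaker X peaks below the M-CSF threshold as the whole cause is argued against, since 139 of the 391 were overlapped, a share 19.1 points below that of autosomal peaks of like fold enrichment and class (difference −19.1, interval −23.3 to −14.8). Fewer reads at the same fold, as the whole cause, are argued against by the difference at like −log10 q, −7.27 points (−11.1 to −3.30). Both comparisons matched on strength in the GM-CSF list, so a loss of X peaks in the M-CSF library itself stays open. Of the 161 M-CSF peaks on X, 139 were overlapped (86.3%). The share expected was 81.6% at like fold enrichment and class (percentile 97.165) and 73.3% at like −log10 q (percentile 100). A difference between the animals or cultures in X may be involved, which was not tested, and the sex of the animals was not given in the sources used here. Both lists held peaks at Y-linked genes, namely Eif2s3y, Kdm5d and Uty in the GM-CSF list and Ddx3y in the M-CSF list, and neither had a peak at Xist.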
